A study of Mus musculus with 19 samples.

How the data were processed

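Gene expression was measured in 19 samples of mouse tibialis anterior muscle, one array per sample, in 4 groups given by the labels: adult wild-type (WT_Adult, 5 arrays), aged wild-type (WT_Aged, 5), adult desmin knockout (KO_Adult, 5) and aged desmin knockout (KO_Aged, 4). Per the labels' protocols, total RNA was extracted with an RNeasy kit and biotinylated cRNA was made by the standard Affymetrix procedure. The deposited values are intensity values on a linear scale, 1 per probe set and array, made with MAS5 per the submitters' processing notes; its version is not given in the sources used here. The table holds 22690 probe sets, of which 64 are control probe sets. Present and absent calls were not used here. The number of arrays limits the precision, and the median standard error over genes rose from 0.22 to 0.35 for aged against adult WT, and from 0.32 to 0.54 for the interaction, with the batch term described below.

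Genes were named from the platform annotation given for the table. Exactly 1 gene symbol belonged to 20380 probe sets, several to 691 and none to 1619; the last 2 kinds were left unnamed and untested. Values were transformed to log2(value + 4.76), the pseudocount being the percentile 10 of all values. The median log2 values of the arrays spanned 0.63, above the limit of 0.5 set for leaving them as they were, so the arrays were quantile normalized. The probe set with the highest mean stood for its gene, and the upper 60% of 12393 genes by mean, 7436 genes, were tested. Probe sets of one gene can disagree: with every probe set tested on its own, 126 genes had probe sets called in both directions between aged and adult WT, 105 for the interaction, 67 between aged KO and WT, 3 between adult KO and WT and 1 between aged and adult KO.

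All 19 arrays entered 1 linear model with a mean per group (limma 3.58.1 in R 4.3.3, lmFit and eBayes), from which 4 pairwise differences and the genotype by age interaction were taken. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. A fold is on the log2(value + pseudocount) scale and understates the change of dim genes. Of 39 gene lists, the 36 with at least 5 tested genes were tested with limma's camera at an inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The model, the lists, the alternatives and the rule for named genes were fixed before the data were examined, from the labels alone.

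The rule named Des; in each pairwise comparison the 10 largest rises and the 10 largest falls among called genes whose 2 groups of arrays did not overlap; for the interaction the 8 largest called values in each direction; and from each list described the 4 members with the smallest p, passing or not, or 3 for markers of another cell type. Clone-style symbols were passed over. Which lists to describe was settled by their test: those that passed are described, with members named where the fit without a batch term passed. A few genes outside the rule are named as such.

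The control probe sets split the arrays. Poly-A spike-in controls and 18S ribosomal RNA gave signal on 8 arrays and almost none on the other 11. This split is called the labelling batch here, after the step at which poly-A controls are usually added; what made it was not tested. It was found after the data were seen, and the following were added then: the batch as a term in the model, only the arrays without the controls, leaving out 2 aged KO arrays with a Gapdh 3' to 5' ratio over 3, and these in combination. A further comparison set KO against WT inside each batch. The batch term can be estimated only through the adult KO arrays, of which 3 carry the controls and 2 do not. Both genotype differences, and both age differences, then rest on the same adult KO arrays, so their correlation was set beside 100 simulations of unchanged groups, drawn for each gene from a normal distribution with its residual spread. In the same way 50 sets of arrays were simulated in which the labelling batch, and 50 in which the 3'-biased arrays, made the only difference between ages. The planned model stays the main one, and values with the batch term are given beside it.

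The alternatives fixed beforehand covered the normalization between arrays, the pseudocount, the filter on dim genes, the choice of probe set, the thresholds, the variance model, array weights, the groups in the fit, the codes in the sample titles as a block or covariate, the correlation in the list test and leaving out each array in turn. As a covariate the title codes were grouped into code blocks A and B. On the WT_Adult, WT_Aged and KO_Adult arrays these blocks match the labelling batch, and they differ from it on the KO_Aged arrays only. A covariate for sex was not run, because Xist and Y-linked signals showed 1 sex only. The model was tested on simulated data made from the real arrays, with 100 genes changed by log2 1 and 100 by log2 2 among 7436. For adult KO against WT it recovered 60% and 96% of them without the batch term, and 31% and 86% with it. For aged against adult WT these were 64% and 95% without the term, and 11% and 77% with it. For the interaction they were 34% and 80%, and 1% and 25%.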

Results

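Muscle was taken 12 h after a bout of 50 eccentric contractions, in which an active muscle is lengthened. The mice were 129/SVE, wild-type or lacking desmin, the intermediate filament protein that links the Z-discs of neighbouring myofibrils. Adults were 7 to 9 weeks old and aged animals 12 to 14 months old. Both genotypes were exercised and no unexercised muscle was analysed here, so every difference is one between exercised muscles. The labels do not state that the arrays of a group came from separate animals, so p-values measure the spread between these arrays, which may be partly technical. Within groups, arrays correlated across genes at r = 0.903 to 0.982 in WT_Adult, 0.961 to 0.979 in WT_Aged, 0.867 to 0.977 in KO_Adult and 0.900 to 0.964 in KO_Aged.

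The control probe sets divided the arrays. The dap poly-A control read 1184 to 3103 on 8 arrays, which were all 5 WT_Aged arrays and KO_Adult replicates 3, 4 and 5, and 1 to 17.4 on the other 11. The middle 18S ribosomal RNA probe set read 5835 to 19660 on the same 8 arrays and 29.1 to 181 on the others. Aged KO against WT, aged against adult WT and the interaction therefore lie across this labelling batch, while adult KO against WT and aged against adult KO lie across it in part. The Gapdh 3' to 5' ratio was 8.61 on KO_Aged replicate 2, 5.01 on KO_Aged replicate 3 and 0.766 to 0.968 on the others. The arrays without controls were not uniform on the first principal component, the direction of largest variance between arrays (38.8%). There WT_Adult replicates 4 and 5 (-3.29 and 1.57) and KO_Aged replicates 1 and 4 (6.62 and 1.26) lay apart from the rest (-46.3 to -21.3). The batch term does not describe this split, and its source was not tested.

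**Figure D1:**
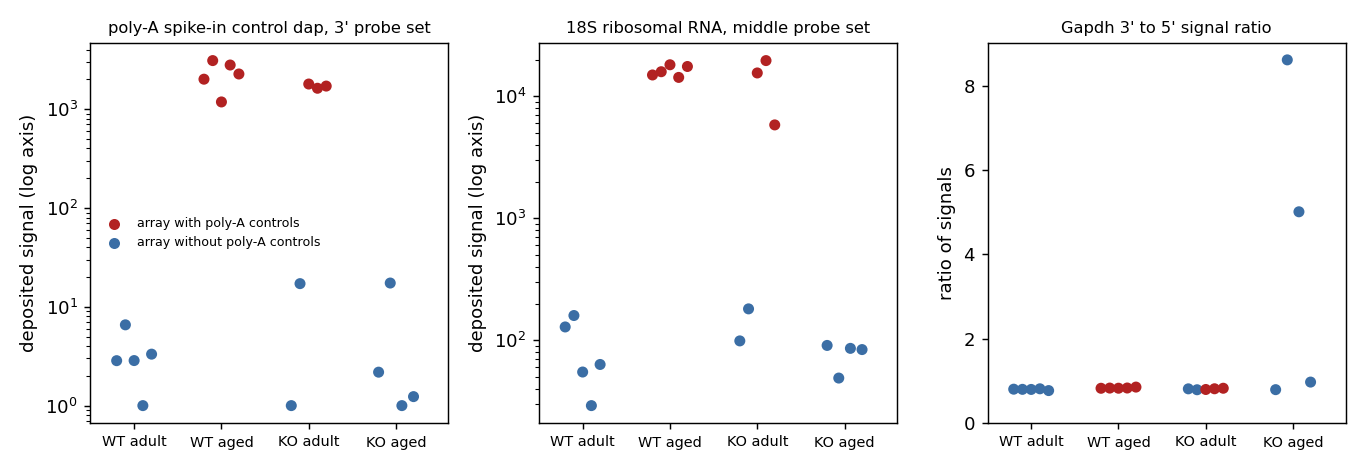
Deposited signals of the dap poly-A control and of the middle 18S ribosomal RNA probe set on log axes, and the Gapdh 3' to 5' ratio on a linear axis, 1 point per array, by group. The 8 arrays with poly-A control signal lie between 1184 and 3103, and 2 KO_Aged arrays have Gapdh ratios of 5.01 and 8.61.

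Des itself was measured first, on every array. The brighter of its 2 probe sets read 18390 ± 4248 (SD, n = 5) in WT_Adult and 11358 ± 796 (SD, n = 5) in WT_Aged, with single arrays from 10749 to 22313. It read 521 ± 218 (SD, n = 5) in KO_Adult and 350 ± 234 (SD, n = 4) in KO_Aged, and no KO array was above 879. On the log2 scale Des fell by 5.00 (SE 0.35) in adult KO muscle and fell by 5.38 (SE 0.37) in aged KO muscle. With the mean of both probe sets the differences were -2.93 and -3.72; the dimmer one read 166 in WT_Adult and 74.7 in KO_Adult, and 286 in WT_Aged and 68.0 in KO_Aged. The 2-sided exact permutation p was 0.00794 in each case, from 252 regroupings of the adult arrays and 126 of the aged ones, the smallest these allow. The values go with the genotype labels of all 19 arrays.

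**Figure D2:**
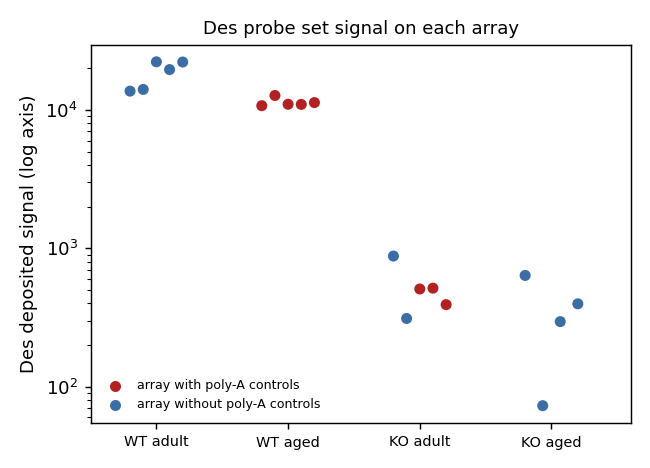
Deposited Des signal (brighter probe set) of each array on a log axis, by group, with the labelling batch in colour. The 10 WT arrays lie between 10749 and 22313 and the 9 KO arrays at or below 879.

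Adult muscle without desmin was compared with adult wild-type muscle to ask what the loss of desmin changes after the contractions. The largest rise was that of Sln (sarcolipin, an inhibitor of the sarcoplasmic reticulum calcium pump), by log2 5.41 (SE 0.44, 42.4-fold). Fetub, which encodes a fetuin, rose by 3.57 (SE 0.37), S100a4, a calcium-binding protein, by 3.29 (SE 0.34), and Fst (follistatin, which binds myostatin and activin) by 2.33 (SE 0.21). Saa3, an acute phase protein, rose by 3.10, Dtl by 2.92, the serpin Serpinb1a by 2.81, the myosin Myo5a by 2.51, Hhatl by 2.45 and the kinase Prkg1 by 2.44. After Des, the largest falls were those of Ybx2, a nucleic acid binding protein, at -4.27 (SE 0.29), the transcription factor E2f4 at -3.32 (SE 0.38), Lpin3 at -2.81 and the Wnt receptor Fzd5 at -2.71. Falls were also called for the lactate transporter Slc16a3 at -2.70, Arhgap10 at -2.57, Ace (angiotensin-converting enzyme) at -2.35, cardiac actin Actc1 at -2.35 and Atn1 at -2.35. All of these separated the 5 KO from the 5 WT arrays.

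Endothelial markers formed the group with the clearest change. Of 18 tested, 15 fell and none rose (18 adjusted over the list alone), with a median log2 difference of -1.15 (camera adjusted p = 1.5e-15, and adjusted p = 0.00328 with an estimated correlation). The receptor Tie1 fell by 1.98 (SE 0.21), with the transcription factor Sox18 at -1.45 (SE 0.16) and the water channel Aqp1 at -1.32 (SE 0.16). With the batch term the median was -1.03 (adjusted p = 2.35e-15, and adjusted p = 0.00917 with an estimated correlation), and 12 fell. In this comparison every value with the term rests on the 2 KO_Adult arrays without poly-A controls alone, against WT_Adult. The arrays without poly-A controls hold the same 2 KO_Adult arrays, so their median was the same and is no separate check. Among them the list passed (adjusted p = 3.97e-14) but not with an estimated correlation (adjusted p = 0.0911 with an estimated correlation, and 0.123 with the 3'-biased arrays left out of the fit). Of 13 smooth muscle and pericyte markers 3 fell and 1 rose (8 and 1 adjusted over the list alone), with a median of -0.52 (adjusted p = 0.0114, and adjusted p = 0.372 with an estimated correlation); Notch3 fell by 0.70, with Tagln at -1.24 and Smtn at -0.94.

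Chaperones were lower as a group: of 17, Hspe1 (-0.64) and Bag3 (-0.87) fell, while Hsph1 at -0.85 (adjusted p = 0.0575) and Dnajb5 at -0.78 (adjusted p = 0.0795) did not pass, and the count adjusted over the list alone was also 2. The list's adjusted p was 0.0232, and adjusted p = 0.718 with an estimated correlation; it rose to 0.107 with no normalization between arrays. Proteasome subunits were higher, 6 of 30 rising and 1 falling, also adjusted over the list alone, with a median of 0.24 (adjusted p = 0.035, and adjusted p = 0.718 with an estimated correlation). Psmd14 rose by 0.72, Psma4 by 0.54 and Psmd12 by 0.39, and Psmb7 fell by 1.35. Glycolysis and glycogen genes had 6 of 21 falling (7 adjusted over the list alone), among them Pkm at -0.78, Gpd1 at -1.24, Pygm at -0.62 and Phkg1 at -0.91 (list adjusted p = 0.00583). Fatty acid genes had 5 of 23 falling (9 adjusted over the list alone), among them Hadha at -1.17, Eci1 at -0.69, Acads at -0.57 and Echs1 at -0.76 (list adjusted p = 0.01). Both had adjusted p = 0.718 with an estimated correlation. These 2 metabolic lists no longer passed with the batch term (0.0668 and 0.223), while chaperones (5.96e-05), proteasome (0.000116) and smooth muscle markers (0.0125) did. With the term these 3 had adjusted p = 0.477, 0.394 and 0.394 with an estimated correlation. With median centring neither metabolic list passed, nor did the chaperones. Slow fibre genes passed with the batch term, at a median of 1.26 and adjusted p = 0.00133, against 0.75 and 0.102 without it (adjusted p = 0.394 and 0.718 with an estimated correlation). The value with the term is that of the 2 KO arrays without poly-A controls alone. Of 12, 4 rose and none fell with the term (6 adjusted over the list alone), and 4 rose and 1 fell without it (5 and 1). Among arrays with the controls, where aged WT was the comparator, 4 were higher and 3 lower, with a median of 0.79.

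Over all 7436 genes, 1241 were called, 544 higher and 697 lower in adult KO, and 2355 had an unadjusted p under 0.05. Without WT_Adult replicate 3 the count was 751, with only the groups compared in the fit 624 and with array weights 3802. The codes in the sample titles gave 652 as a random block, 496 as a covariate and 75 within 1 code block. For this comparison that covariate is the same as the labelling batch. With median centring the split was 916 higher and 368 lower, and with no normalization 421 and 996; median centring moved the median of all genes from 0.04 to 0.20. A fit with the batch term called 496 genes, 345 of them also called in the same direction without it, and among the arrays without poly-A controls 106 were called. Of the 40 called genes named, 22 kept their call with the term. Saa3, Dtl, Prkg1, Atn1, Hspe1, Psma4, Psmb7, Psmd12, Tagln, Smtn and the metabolic genes did not. Standard errors of the genes named ran from 0.11 to 0.77. The groups did not overlap for 749 genes, where chance gives 0.794%.

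**Figure D3:**
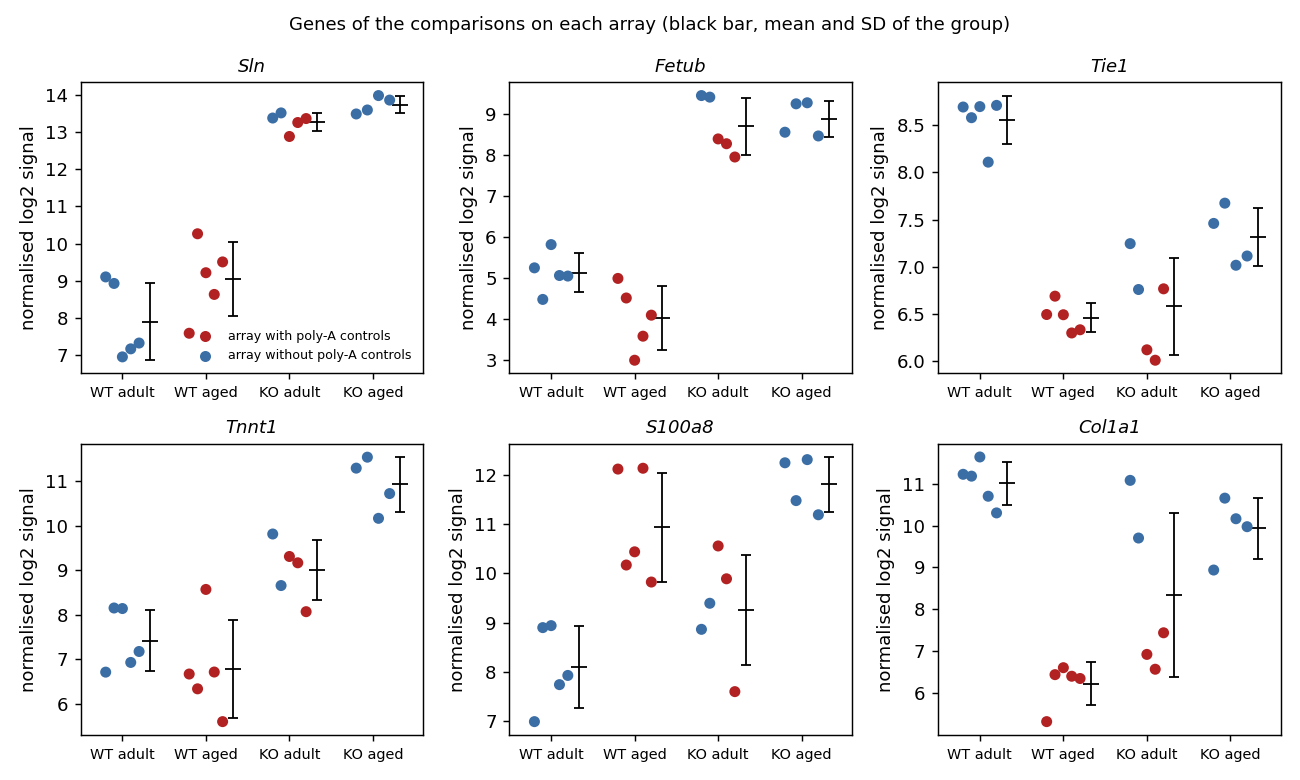
Normalised log2 signal of Sln, Fetub, Tie1, Tnnt1, S100a8 and Col1a1 on each array, by group, with the labelling batch in colour and bars for the group mean and SD. Sln and Fetub are higher in KO at both ages, and Col1a1 has its lowest group mean in WT_Aged.

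Genotype was next compared inside each labelling batch, with no array shared: 2 KO_Adult against 5 WT_Adult arrays without poly-A controls, and 3 KO_Adult against 5 WT_Aged arrays with them, where age differs too. They called 496 and 694 genes, with 195 called in both and 190 of these in the same direction. The 112 higher in KO in both compare with 12.2 expected of independent lists, and the 78 lower with 10.97. Sln was higher by 5.57 and 4.14, Fetub by 4.30 and 4.18 and S100a4 by 3.10 and 2.50. Fzd5 differed by -3.02 and -3.31 and Lpin3 by -2.81 and -2.11. Differences across all genes correlated at r = 0.37, and genes are not independent replicates. The endothelial list had medians of -1.03, the value of the batch term again, and -0.60. Tie1 had -1.55 (adjusted p = 0.00102) without the controls but -0.16 (adjusted p = 0.690) with them.

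**Figure D4:**
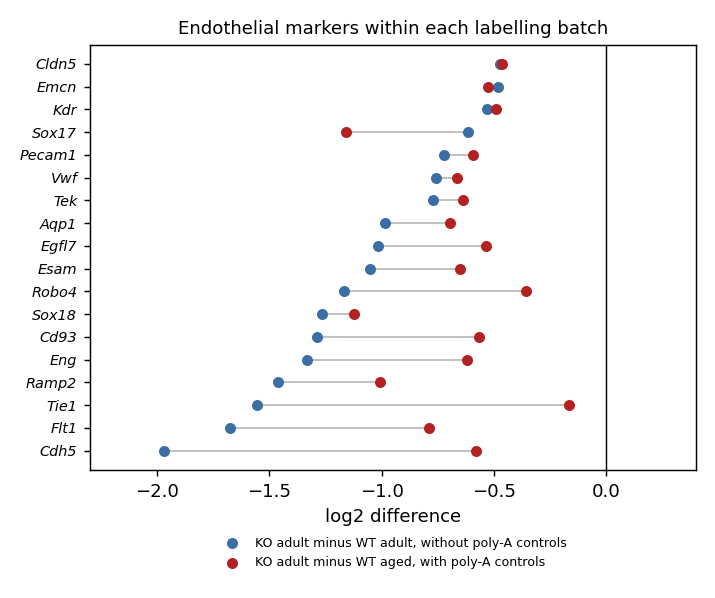
Log2 difference of 18 endothelial markers between KO and WT in each labelling batch, adult KO minus adult WT without poly-A controls and adult KO minus aged WT with them. The medians are -1.03 and -0.60, and every marker lies below 0 in both.

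In aged muscle the same question was asked of KO against WT. Fetub rose by log2 4.86 (SE 0.39, 29.0-fold) and Sln by 4.71 (SE 0.47). Genes of slow fibres rose with them: the myosin light chain Myl2 by 4.36 (SE 0.70), and the slow troponins Tnnt1 by 4.16 (SE 0.49), Tnni1 by 3.38 and Tnnc1 by 3.29. Col1a1, a chain of type I collagen, rose by 3.71, the replication factor Mcm6 by 3.23, Npnt (nephronectin) by 3.14 and Trim35 by 3.06. After Des, the largest falls were those of the globin Hbb-b2 at -4.19 (SE 0.82), Hnrnpl at -4.16, the activity-induced gene Arc at -4.11 (SE 0.74) and Arf5 at -4.05. Falls were also called for Fzd5 at -3.73, Prcc at -3.71, the chaperone Dnajb1 at -3.64, the matrix protease Mmp10 at -3.63 and Stk25 at -3.63.

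Of 12 slow fibre genes 9 rose and none fell, also adjusted over the list alone, with a median of 3.02 (adjusted p = 1.18e-05, and adjusted p = 0.76 with an estimated correlation). Myoz2 rose by 2.75 and the calcium pump Atp2a2 by 2.35, beside Sln and Tnnt1. Of 23 immediate early genes, transcripts switched on soon after a stimulus, 11 fell (14 adjusted over the list alone), with a median of -1.32 (adjusted p = 3.19e-06, and adjusted p = 0.792 with an estimated correlation). Jun fell by 2.35, with Btg2 at -3.31, Klf4 at -1.86 and Maff at -1.83. Of 17 chaperones 11 fell (13 adjusted over the list alone), with a median of -0.95 (adjusted p = 3.26e-05, and adjusted p = 0.792 with an estimated correlation), among them Dnaja1 at -2.19, Dnajb5 at -1.24 and Hspa1a at -2.41. Endothelial markers fell in 8 of 18 and rose in 1 (9 and 1 adjusted over the list alone), with a median of -0.53 (adjusted p = 0.00364, and adjusted p = 0.76 with an estimated correlation); Sox17 fell by 1.72, with Sox18 at -0.94 and Egfl7 at -0.77. Matrix genes rose in 13 of 37 and fell in 2 (14 and 2 adjusted over the list alone), with a median of 0.60 (adjusted p = 0.0143, and adjusted p = 0.911 with an estimated correlation). Beside Col1a1, the rule named Lama2, up by 1.21, and Col3a1, up by 1.85.

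In all, 2190 genes were called, 1259 higher and 931 lower, and 3064 had an unadjusted p under 0.05. The batch term left 408 called, 240 of them also called in the same direction without it, and 1851 had an unadjusted p under 0.05. Of the 34 genes named, 13 kept their call: Des, Fetub, Sln, Tnnt1, Mcm6, Npnt, Hbb-b2, Fzd5, Myoz2, Atp2a2, Sox17, Sox18 and Lama2. With the term the slow fibre (adjusted p = 0.0101), immediate early (0.0101) and endothelial (0.00364) lists passed, while chaperones (0.384) and matrix genes (0.928, median -0.16) did not. The 3 that passed had adjusted p = 0.974 with an estimated correlation. Col1a1 moved to 0.30 (adjusted p = 0.801) and Trim35 to -0.22 (adjusted p = 0.880). Without the 2 arrays of high Gapdh ratio 1059 genes were called, 498 higher and 561 lower. Standard errors of the genes named ran from 0.15 to 0.86, and the groups did not overlap for 2321 genes, where chance gives 1.59%.

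Aged and adult wild-type muscle were compared for what age changes after the contractions, a difference that lies wholly across the labelling batch. Genes of inflammatory cells were higher in the aged arrays: the macrophage gene Chil3 by log2 3.41 (SE 0.62), Saa3 by 3.39 (SE 0.77), Slfn4 by 3.25, the neutrophil gene S100a9 by 3.20 (SE 0.65) and the scavenger receptor Msr1 by 2.90. The noncoding RNA Malat1 was higher by 4.39 (SE 1.16), Atp13a3 by 3.07, Ccdc71l by 3.06, Dtl by 3.05 and the transcription factor Runx1 by 2.93. Col1a1 fell by 4.78 (SE 0.65), followed by Trim35 at -3.98, Slc16a3 at -3.43, the kinase Pdk2 at -3.32, E2f4 at -3.09, Atn1 at -2.85, the nucleoside transporter Slc29a1 at -2.77, Ybx2 at -2.76, Ltbp4 at -2.72 and the collagen Col15a1 at -2.69. Des, at -0.48 (SE 0.35), did not pass (adjusted p = 0.277).

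All 5 tested neutrophil markers rose, also adjusted over the list alone (median 2.26, adjusted p = 0.00502), with S100a8 at 2.85 and Il1r2 at 2.06. Macrophage markers rose in 9 of 21, also adjusted over the list alone (median 1.02, adjusted p = 0.00484), with Mrc1 at 1.16. Chemokines and cytokines rose in 13 of 20 (13 rose and 1 fell adjusted over the list alone; median 1.01, adjusted p = 0.00439), with Socs3 at 2.74, Ccl2 at 2.06, Ccl7 at 2.15 and Csf1 at 0.93. Immediate early genes rose in 9 of 23, also adjusted over the list alone (median 0.94, adjusted p = 0.00273), with Klf4 at 1.74, Myc at 1.63, Klf6 at 1.90 and Maff at 1.44. Chaperones rose in 6 of 17 and fell in 1, also adjusted over the list alone (median 0.44, adjusted p = 0.0484), with Chordc1 at 1.64, Dnajb4 at 1.49, Cryab at 0.36 and Dnajb5 at -1.13. Endothelial markers fell in 8 of 18 and rose in 1 (10 and 1 adjusted over the list alone; median -0.43, adjusted p = 0.00484), with Tie1 at -2.10, Pecam1 at -1.64 and Aqp1 at -0.85. Fatty acid genes fell in 12 of 23 and rose in 2 (14 and 2 adjusted over the list alone; median -0.67, adjusted p = 0.00439), with Hadha at -1.93, Mlycd at -1.12, Pnpla2 at -1.67 and Acads at -0.76. Glycolysis and glycogen genes fell in 10 of 21, also adjusted over the list alone (median -0.22, adjusted p = 0.00502), with Pkm at -1.47, Gys1 at -1.59, Pygm at -0.99 and Phkg1 at -1.47. Oxidative phosphorylation genes fell in 17 of 55 and rose in 2, also adjusted over the list alone (median -0.19, adjusted p = 0.00815), with Sdhc at -1.64, Atp5a1 at -0.72, Cyc1 at -0.63 and Ndufa9 at -0.56. With median centring or no normalization the chaperones did not pass. None of these lists passed with an estimated correlation, the lowest adjusted p = 0.569 with an estimated correlation.

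In all, 2891 genes were called, 1346 higher and 1545 lower (1621 and 1016 with median centring, which moved the median of all genes from -0.03 to 0.08), and 3627 had an unadjusted p under 0.05. The count was 4627 with array weights and 7 with the title codes as a covariate, which for this comparison is the same as the batch term. With the batch term limma called 7, with 1054 at an unadjusted p under 0.05; of the 50 called genes named only Ybx2 kept its call, at -2.80 (adjusted p = 0.0450). The other 6, named after their values were seen, were Fhl2 (3.37), Tmem100 (2.25), Fst (2.02), Cyfip2 (1.85), Efemp1 (1.80) and Deaf1 (-1.68). With the term Malat1, Atp13a3, Runx1, Chordc1 and Dnajb4 had values below 0 and Slc29a1 and Cyc1 above 0, none of which passed. The lists for macrophages (adjusted p = 2.27e-06), neutrophils (0.00727), chemokines (0.00133), endothelium (0.00358), immediate early genes (0.0431) and oxidative phosphorylation (0.0494) passed with the term, and those for chaperones (0.875), glycolysis (0.0578) and fatty acid use (0.0938) did not. The 6 that passed had adjusted p = 0.426 to 0.609 with an estimated correlation. With the term these values subtract the difference between KO_Adult arrays with and without poly-A controls, so they carry the levels of those KO arrays. One array without controls, KO_Adult replicate 2, was the highest of its group for the mean of the macrophage markers (9.18, the others 8.41). Standard errors of the genes named ran from 0.13 to 1.16, and the groups did not overlap for 2186 genes, where chance gives 0.794%.

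The age difference was then taken in muscle without desmin. The largest rise was that of Myl2, by log2 3.26 (SE 0.70), followed by the neutrophil genes S100a9 by 2.63 (SE 0.68) and S100a8 by 2.55 (SE 0.58). The inflammatory serpin Serpina3n rose by 2.40, Asns (asparagine synthetase) by 2.35 (SE 0.30) and the mitochondrial folate enzyme Mthfd2 by 2.14 (SE 0.26). The leukocyte gene Cd53 rose by 2.03, Fcer1g by 1.96, Tnnt1 by 1.93 and the chemokine Cxcl14 by 1.92. Hnrnpl fell by 3.42, followed by Gdpd3 at -3.39 (SE 0.93), Stk25 at -3.15, the transcription factor Usf1 at -2.66 (SE 0.32), Clec2d at -2.57, Dusp18 at -2.46, Clec3b at -2.40, Mpst at -2.35, the cell cycle inhibitor Cdkn1b at -2.31 and Retreg3 at -2.14. Des, at -0.86 (SE 0.37), did not pass (adjusted p = 0.161).

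Slow fibre genes rose in 5 of 12 (7 adjusted over the list alone; median 1.63, adjusted p = 6.35e-05), with Atp2a2 at 1.79 and Tnnc1 at 1.67. Genes of endoplasmic reticulum stress rose in 3 of 17 (7 rose and 1 fell adjusted over the list alone; median 0.46, adjusted p = 0.0016), with Trib3 at 1.78 and Pdia6 at 0.78, while Creld2 at 0.86 did not pass. Neutrophil markers rose in 3 of 5 (5 adjusted over the list alone; median 1.70, adjusted p = 0.0016), with Mmp9 at 1.53. Chemokines rose in 3 of 20 (8 rose and 1 fell adjusted over the list alone; median 0.94, adjusted p = 0.0016), with Ccl9 at 1.59 and Il4ra at 1.26, while Ccl8 at 1.58 did not pass. Macrophage markers rose in 4 of 21 and fell in 1 (5 and 1 adjusted over the list alone; median 0.86, adjusted p = 0.00206), with Mrc1 at 1.13 and the complement gene C1qa at -1.98. No complement or acute phase gene of 9 passed (4 adjusted over the list alone), with Lbp at 0.88, Lcn2 at 1.20, C1ra at 0.67 and Serping1 at 0.76 and a median of 0.88 (adjusted p = 0.00517). Matrix genes rose in 5 of 37 (6 adjusted over the list alone; median 0.51, adjusted p = 0.00517), with Col4a1 at 0.88, Col4a2 at 0.91 and Loxl1 at 0.93. Oxidative phosphorylation genes fell in 4 of 55, also adjusted over the list alone (median -0.09, adjusted p = 0.00206): Atp5pb at -0.48, Cox7a1 at -0.51, Ndufb8 at -0.41 and Atp5h at -0.44. Genes of excitation-contraction coupling fell in 2 of 12 (3 adjusted over the list alone; median -0.31, adjusted p = 0.0157), Asph at -1.35 and Camk2b at -0.96, while Mtmr14 at -0.74 and Ryr1 at 0.36 did not pass. None of these lists passed with an estimated correlation, the lowest adjusted p = 0.531 with an estimated correlation.

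In all, 553 genes were called, 274 higher and 279 lower (166 and 301 with median centring, 477 and 227 with no normalization), and 1733 had an unadjusted p under 0.05. The count was 51 with only the groups compared in the fit, 357 with no filter on dim genes, 1268 with array weights, 1399 with the title codes as a covariate and 1654 within 1 code block. The last 2 settings compare KO_Aged, without poly-A controls, with KO_Adult replicates 3, 4 and 5 only, which carry them. They lie wholly across the labelling batch, so their higher counts are not separated from it. The batch term gave 742 calls, 237 of them also called in the same direction without it, and 22 of the 38 called genes named kept their call, S100a8, Asns, Mthfd2, Trib3, Atp2a2, Usf1 and C1qa among them. The lists for endoplasmic reticulum stress (adjusted p = 0.00692), neutrophils (0.0254), chemokines (0.0254) and oxidative phosphorylation (0.00692) passed with the term, and the others did not. These 4 had adjusted p = 0.909 with an estimated correlation. With the 3'-biased arrays left out as well, chemokines no longer passed (0.0692). Among arrays without poly-A controls, leaving those out took oxidative phosphorylation from 0.0088 to 0.0513, slow fibre genes from 0.0498 to 0.0941 and the macrophage median from 0.47 to 0.16 (adjusted p = 0.957 with an estimated correlation for each). Without the batch term it ended the call of excitation-contraction coupling (0.607) and took the macrophage median to 0.44 and the matrix median to 0.24. Among the 11 arrays without poly-A controls limma called 5 genes, with 1615 at an unadjusted p under 0.05: Mthfd2 (2.49) and Clec2d (-3.05), and, named after their values were seen, Csf2ra (1.69), Serhl (-1.33) and Commd9 (-1.92). Without the 2 arrays of high Gapdh ratio 117 genes were called, 27 higher and 90 lower, while with the batch term as well the split was 446 and 495. With the term this difference rests on KO_Aged replicates 1 and 4 against KO_Adult replicates 1 and 2, which lay apart on the first principal component. The count was 191 without KO_Aged replicate 3 alone and 318 without KO_Adult replicate 5. Standard errors of the genes named ran from 0.11 to 0.93, and the groups did not overlap for 605 genes, where chance gives 1.59%.

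The interaction asks whether the genotype difference itself changed with age. It was called for 1864 genes, 1060 with a positive value and 804 with a negative one (625 and 1087 with median centring, 1480 and 602 with no normalization, which moved the median of all genes from 0.03 to -0.14 and to 0.17), and 2821 had an unadjusted p under 0.05. The count was 3935 with array weights and 672 with the title codes as a covariate. The largest positive values were those of Col1a1 at 6.37 (SE 0.94), Trim35 at 4.78, Atn1 at 4.75, Myl2 at 4.67 (SE 0.96), E2f4 at 4.63, Col15a1 at 4.58, Pdk2 at 4.44 and the superoxide dismutase Sod3 at 4.43. The most negative were those of Malat1 at -5.51 (SE 1.70), Stk25 at -5.41, Prcc at -5.37, Arf5 at -5.11, Arid5b at -4.44, Prkg1 at -4.13, Sp3 at -4.02 and Pdia4 at -4.01. Des, at -0.38 (SE 0.51), did not pass (adjusted p = 0.605).

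By list, slow fibre genes had 6 of 12 positive (8 adjusted over the list alone; adjusted p = 0.00827), with Myoz2 at 1.89, Atp2a2 at 1.64 and Tnnt1 at 2.58. Immediate early genes had 10 of 23 negative, also adjusted over the list alone (adjusted p = 0.00227), with Klf4 at -2.24, Btg2 at -3.41, Maff at -1.88 and Klf6 at -2.12. Matrix genes had 12 of 37 positive and 2 negative (16 and 2 adjusted over the list alone; adjusted p = 0.00827), with Col4a1 at 1.31 and Col4a2 at 1.81. Endothelial markers had 8 of 18 positive and 1 negative, also adjusted over the list alone (adjusted p = 0.00827), with Tie1 at 2.83, Pecam1 at 1.85 and Vwf at 1.86. Glycolysis and glycogen genes had 5 of 21 positive, also adjusted over the list alone (adjusted p = 0.00827), with Pkm at 2.16, Pygm at 1.48, Gys1 at 1.48 and Ldhb at 1.48. Fatty acid genes had 8 of 23 positive, also adjusted over the list alone (adjusted p = 0.0126), with Hadha at 2.65, Cpt2 at 1.51, Hadhb at 0.91 and Pnpla2 at 1.71. Each of the 6 lists had adjusted p = 0.974 with an estimated correlation, and with median centring the last 2 did not pass. For the interaction limma called 2 genes with the batch term, with 1229 at an unadjusted p under 0.05: Deaf1 at 2.62 and Grb14 at -2.57, both named after their values were seen. None of the 36 called genes named above and none of the lists passed with the term.

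The genotype differences at the 2 ages correlated across genes at r = -0.03 (Spearman's rho -0.11). Of the called genes 155 were higher in KO at both ages, where independent lists give 92.1, 123 were lower at both, where they give 87.3, and 222 went in opposite directions. All comparisons share 1 spread per gene, so overlaps in either direction can exceed those of independent lists without a shared response. The age differences of the 2 genotypes correlated at r = -0.10 (rho -0.09), with 49 genes higher in aged muscle of both (49.6 from independent lists), 46 lower in both (58.0) and 154 in opposite directions. In the fit with the batch term the correlations were -0.03 and -0.24, but both differences of a pair then rest on the 2 KO_Adult arrays without poly-A controls, with opposite signs. In 100 simulations of unchanged groups in that fit the mean correlations were -0.53 and -0.52. The covariances were -0.0145 for genotype and -0.0904 for age, against simulated means of -0.0806 for each. With the term 38 genes were higher in KO at both ages, where independent lists give 7.80, 21 were lower at both, where they give 5.87, and 7 went in opposite directions; the values for independent lists leave out the shared arrays. For age, 1 gene went in opposite directions in the 2 genotypes with the term and limma called none the same way in both, as it called 7 genes in WT. With the title codes as a covariate both correlations turned, to 0.42 and 0.35, with array weights they were -0.21 and -0.39, and without the 3'-biased arrays 0.031 and 0.071. With that covariate both age differences subtract the KO_Adult arrays with poly-A controls, which by itself raises their correlation, and no simulation was run for it. The jackknife standard errors over arrays of the correlations without a covariate were 0.22 and 0.32. These are correlations across genes, which are not independent replicates.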

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

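The tests of the labelling batch, of age and of the 3'-biased arrays below were chosen after the results they bear on were seen; the counts over regroupings of the arrays were set before.

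Signals outside the genes were the first to stand out. The lowest dap poly-A control signal among the 8 arrays with it was 1184, against at most 17.4 on the other 11, and the lowest signal of the middle 18S ribosomal RNA probe set was 5835, against at most 181.

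The interaction test called 1864 genes, but it lies across the labelling batch: with the batch term limma called 2, with 1229 at an unadjusted p under 0.05, and 0 (1842) without the 3'-biased arrays as well. A change of the genotype difference with age is therefore not separated from the batch for these genes. Named ones with positive values were Col1a1 (6.37), Trim35 (4.78), Atn1 (4.75), Myl2 (4.67), E2f4 (4.63), Col15a1 (4.58), Pdk2 (4.44), Sod3 (4.43), Tie1 (2.83), Hadha (2.65), Tnnt1 (2.58), Pkm (2.16), Myoz2 (1.89), Vwf (1.86), Pecam1 (1.85), Col4a2 (1.81), Pnpla2 (1.71), Atp2a2 (1.64), Cpt2 (1.51), Pygm (1.48), Gys1 (1.48), Ldhb (1.48), Col4a1 (1.31) and Hadhb (0.91). Those with negative values were Malat1 (-5.51), Stk25 (-5.41), Prcc (-5.37), Arf5 (-5.11), Arid5b (-4.44), Prkg1 (-4.13), Sp3 (-4.02), Pdia4 (-4.01), Btg2 (-3.41), Klf4 (-2.24), Klf6 (-2.12) and Maff (-1.88). None of these 36 genes passed with the batch term.

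Of 100 regroupings of the arrays, the real one included, 1 gave as many called genes for aged KO against WT (2190, highest other 506), 1 for aged against adult WT (2891, highest other 1) and, with residuals rearranged, 1 for the interaction (1864, highest other 755). For adult KO against WT 2 did (1241, highest other 1297) and for aged against adult KO 4 did (553, highest other 2040). Chance alone is thereby excluded for the first 3, but only against regroupings that mix the arrays with poly-A controls. For the first 2 no other regrouping kept these arrays on one side, so the labelling batch alone could rank the real grouping first. The interaction lies across the batch too, and the rearranged residuals take no account of it. The highest others of the last 2 kept all arrays with poly-A controls on one side, as the real groupings do, which points to a structure of the arrays, and the highest that mixed them were 163 and 18. Chance is excluded for these 2 over all regroupings only: with the arrays with poly-A controls kept on one side, 2 of 15 and 4 of 16 gave as many genes, and so few regroupings cannot give a share under 0.05. A fit with the batch term called 496 and 742 genes in these 2 comparisons, and the arrays without poly-A controls gave 106 and 5.

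The first pattern weighed is the large difference between aged and adult WT, with the aged KO against WT difference that shares its WT_Aged arrays. The difference between the adult KO arrays of the 2 labelling batches, which shares no array with aged against adult WT, correlated with it at r = 0.71 across genes, which is consistent with the labelling batch as a source of much of it. Of the called genes, 73.3% kept their direction with the batch term. Simulated arrays in which the batch made the only difference gave 62.5% (60.1% to 64.0%), because both values rest on the same WT arrays. The observed share lay above every simulated one, but it cannot decide whether the batch was the only source. The simulated genes varied independently of each other, unlike real genes, so that range is too narrow. The simulated batch difference was that measured between 3 and 2 KO_Adult arrays, noise included, and may be too large. These simulations called 3406 to 3569 genes, more than the 2891 of the data. Age and batch cannot be told apart for most of these genes. The same batch difference correlated with aged KO against WT at r = -0.51, and 79.0% of the genes called there lay opposite to it, as the WT_Aged arrays carry the controls. Against the batch as the whole source of that difference, 408 genes were called with the term, though the batch may have set the size and number of the others.

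The second pattern is the difference between aged and adult KO. Against the 2 arrays with high Gapdh ratios as its whole source, 163 of the 553 called genes were also called, in the same direction, without those arrays and with the batch term. For this difference that fit sets KO_Aged replicates 1 and 4 against KO_Adult replicates 1 and 2. On the first principal component these lay at 6.62 and 1.26 against -39.0 and -38.4. The 163 genes are therefore not separated from that split of the arrays, which the batch term does not describe. Against the labelling batch as the whole source, 237 were also called with the term. In 50 simulations of each source alone the matching count was 0. The matching fit removes the source simulated, so this 0 was fixed beforehand and adds nothing. Before that fit, the simulations called 0 to 187 genes for the batch alone and 0 to 11 for the 3'-biased arrays alone. The 163 and 237 genes were called with a spread shared by all groups. Among arrays without poly-A controls limma called 5 genes, or 12 without the 3'-biased ones. Either source may have set part of the difference, and age stays open and was not tested apart from them.

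Single arrays stood far from the rest of their group in 23 of 680 group tests. Chance gives about 1 in 20, so this is no excess of outlying arrays. Values are normalised log2, except for the Gapdh ratio. WT_Aged replicate 1 was lowest for Col1a1 (5.32), Dnajb1 (11.90), Dnaja1 (12.88) and the mean of the chaperones (12.95), and highest for Fst (7.96). Other WT_Aged arrays stood out for Psmd12 (replicate 4, lowest, 11.81), Arf5 (replicate 3, highest, 9.08), Trib3 (replicate 5, lowest, 4.65) and the Gapdh 3' to 5' ratio (replicate 5, highest, 0.849). In WT_Adult these were Tie1 (replicate 4, lowest, 8.11), Serpina3n (replicate 4, lowest, 7.74), Acads (replicate 3, highest, 11.31), Pecam1 (replicate 3, highest, 10.59) and Ryr1 (replicate 2, lowest, 13.79). KO_Adult replicate 2 was lowest for Ryr1 (13.24) and highest for the mean of the macrophage markers (9.18). In KO_Aged, replicate 1 was lowest for Smtn (8.79) and highest for Jun (11.69), replicate 2 was lowest for Mrc1 (8.89) and Serpina3n (12.15) and highest for Cox7a1 (13.65), and replicate 4 was lowest for Chil3 (7.80) and Ccl2 (8.34).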

How the results depend on the processing

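Of the settings run, 36 were planned and 5, those on the labelling batch and the 3'-biased arrays, were chosen after seeing the data. Except where a setting itself left out genes or arrays, the cause of a change was not tested. Des kept its direction and call in every setting that gave it a value, at -2.93 and -3.72 with the mean of the probe sets. A covariate for sex was not run, since the arrays showed 1 sex only. Counts of called genes that moved by more than 1.5 times are given in the order adult KO against WT, aged KO against WT, aged against adult WT, aged against adult KO and interaction, as far as they moved. With at least a 2-fold difference they were 397, 916, 1111 and 228, and at an adjusted p under 0.01 they were 504, 1150, 1510, 114 and 804. With no filter on dim genes aged against adult KO had 357. With array weights all but aged KO against WT moved, to 3802, 4627, 1268 and 3935. With only the groups of the comparison in the fit, adult KO against WT had 624 and aged against adult KO 51. No paired analysis was possible because the replicate numbers follow accession order and pair nothing. The codes in the titles, whose meaning the labels do not give, were used as a random block (correlation 0.286) and gave 652 for adult KO against WT, and the list test was not run there. As a covariate, grouped into code blocks, they gave 496, 7 for aged against adult WT, 1399 for aged against adult KO and 672 for the interaction. The blocks match the labelling batch except on the KO_Aged arrays, so 496 and 7 are the counts of the batch term again. This covariate moved the correlations of the genotype and age differences to 0.42 and 0.35. Within 1 code block adult KO against WT had 75 and aged against adult KO 1654. The counts of 1399 and 1654 set KO_Aged arrays without poly-A controls against KO_Adult arrays with them, wholly across the labelling batch. Of 180 list tests 35 passed, and 1 with an estimated correlation. Normalization, pseudocount, the probe set rule and the variance model moved no total count by more than 1.5 times. Normalization did move the split by direction, in adult KO against WT from 544 higher and 697 lower to 916 and 368 with median centring. Median centring ended 16 and no normalization 1 of the 193 calls of named genes, and the mean of the probe sets ended 12 of 190. The mean of the probe sets also turned the direction of 1 more called gene, Atp5a1, which did not pass there.

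With the batch term the counts were 496, 408, 7 and 2, aged against adult KO staying within 1.5 times. Among arrays without poly-A controls adult KO against WT had 106 and aged against adult KO 5. Without the 3'-biased arrays aged KO against WT had 1059, aged against adult KO 117 and the interaction 1083. With the batch term and without those arrays the counts were 591, 560, 5, 941 and 0 (limma; 1842 at an unadjusted p under 0.05), and among arrays without poly-A controls and without them 115 and 12. The batch term without those arrays ended 133 of the 196 calls of named genes, and the title code covariate 70. That covariate also turned the direction of 7 more called genes, none of which passed with it.

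Directions turned in these cases. For aged against adult WT, the batch term, with or without the 3'-biased arrays, and the title code covariate each gave Malat1 -0.21, Atp13a3 -0.38, Runx1 -0.60, Slc29a1 0.074, Chordc1 -0.42, Dnajb4 -0.71 and Cyc1 0.014, a median of -0.043 for the chaperones and 0.56 for fibroblast markers. These are 1 estimate and not separate checks, because both covariates match on the arrays it uses and no KO_Aged array enters it. The mean of the probe sets gave Atp5a1 0.26. For aged KO against WT the batch term gave Trim35 -0.22 and a median of -0.16 for matrix genes, and without the 3'-biased arrays -0.18 for both Col1a1 and that median. For aged against adult KO the matrix genes had a median of 0.51; it was -0.098 with the batch term, also among arrays without poly-A controls, where the list test still pointed up, and -0.12 in both without the 3'-biased arrays. Leaving out those arrays alone gave 0.24. For the interaction the batch term gave Trim35 -0.47, Malat1 1.85, Prkg1 0.44, Sp3 1.14, Pecam1 -0.55 and a matrix median of -0.34. Without the 3'-biased arrays as well it gave Malat1 3.63, Prkg1 1.30, Sp3 2.34, Pecam1 -0.53, Vwf -0.17 and a matrix median of -0.49.

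Leaving out 1 array at a time, adult KO against WT ranged from 751 (without WT_Adult replicate 3) to 1521, aged KO against WT from 1562 to 2313, aged against adult WT from 2135 to 3098, aged against adult KO from 191 (without KO_Aged replicate 3; 318 without KO_Adult replicate 5) to 724 and the interaction from 1386 to 2319. Des ranged from -5.21 to -4.86 in adult and from -5.75 to -4.86 in aged muscle, the list tests passed from 31 to 40, and the correlations ranged from -0.14 to 0.09 and from -0.26 to 0.06. The number of arrays limits the precision. The filter left out only the genes with the lowest means over all arrays. Tested genes had means down to log2 6.32, below the median of 6.78 over all probe sets. Some were dim in 1 group, such as Col1a1 in WT_Aged (5.32 on replicate 1, the others 6.45).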

Other observations

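The tests of the endothelial list below were chosen after its values were seen, as was the batch term in the paragraph before them.

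Some gene groups not described above did not pass without the batch term and passed with it. In adult KO against WT, complement and acute phase genes had a median of 0.91 (adjusted p = 0.0215) and macrophage markers of 0.77 (adjusted p = 0.0215), against 0.26 and 0.42 without the term. These medians with the term are those of the 2 KO arrays without poly-A controls alone. Genes of endoplasmic reticulum stress had a median of -0.19 (adjusted p = 0.0459), but did not pass among the arrays without poly-A controls (adjusted p = 0.0563). In aged KO against WT the 6 tendon and cartilage markers had a median of -1.33 (adjusted p = 0.0425), which did not pass without the 3'-biased arrays (adjusted p = 0.139). In aged against adult WT complement and acute phase genes had 0.92 (adjusted p = 0.000238), tendon and cartilage markers 1.07 (adjusted p = 0.0175) and fibroblast markers 0.56 (adjusted p = 0.0494). The Z-disc list had -0.26 (adjusted p = 0.0431), citric acid cycle genes -0.20 (adjusted p = 0.0431) and insulin action -0.26 (adjusted p = 0.0494). None of these passed with an estimated correlation: adjusted p = 0.576 to 0.635 with an estimated correlation in adult KO against WT, 0.974 in aged KO against WT and 0.426 to 0.527 in aged against adult WT. Inside the labelling batches the macrophage markers of adult KO minus WT had medians of 0.77 without and -0.60 with poly-A controls, and complement genes 0.91 and -0.18. With the controls aged WT was the comparator, and without them adult WT. Neither direction held in both, but the age of the comparator differs too. Macrophage markers were higher in aged than in adult WT above, so the turn in sign does not show that the genotype difference was inconsistent.

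The third pattern weighed is the lower level of endothelial markers in adult KO muscle. Against the labelling batch as its source, the median was -0.60 among arrays that all carried poly-A controls, where aged WT was the comparator, and -1.03 among those that did not. A lower share of every cell type other than muscle fibres stays open: the 126 members of the other cell type lists had a median of 0.23 with the batch term (quartiles -0.36 to 0.73), a value set by the 2 KO arrays without controls, but -0.35 with the controls (quartiles -0.77 to 0.16), where macrophage markers (-0.60), lymphocyte markers (-0.70), neutrophil markers (-1.30) and tendon markers (-1.12) were as low as the endothelial ones or lower, while fibroblast (0.022), satellite cell (-0.047), Schwann cell (-0.10), smooth muscle (-0.26) and adipocyte markers (-0.39) were not. All 18 tested markers were below 0 in both batches, which is consistent with fewer endothelial cells or lower expression in them, a hypothesis found and tested on the same arrays. The 2 cannot be separated in RNA from whole muscle. Single markers such as Tie1 (-0.16 with the controls) differed between the 2 comparisons, in which the age of the WT comparator changes along with the batch.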
